A study of Mus musculus with 4 samples.

How the data were processed

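RNA of Foxp3-transduced and of control vector-transduced mouse activated T cells was hybridised to 4 2-colour microRNA arrays, per the labels, with 2 arrays of exchanged dyes at 72 h and 2 at 96 h. The labels give the RNA and dye of each channel. Groups were the time points, and the replicate number stood for the dye orientation. The values used were those of the authors' deposited value table, taken as log2 ratios of the channels of each array. The scanner, the background correction, the normalization and the direction of the ratio were not given in the sources used here, and no scanner intensities were used here. The values ran from -2.27 to 5.10. Base 10 would exceed the range of a 16-bit scanner, whose largest log10 ratio is 4.82, while natural logs could not be ruled out, so every fold below rests on base 2. Column medians over miRNA probes were -0.59 and -0.83 at 72 h and 1.27 and 0.02 at 96 h (replicates 1 and 2), so the arrays shared no centring.

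The table held 178 probes, of which 7 were control RNAs (3 small nuclear RNAs and 4 tRNAs) and were left out of the tests. The platform annotation gave 1 gene symbol for 61 probes and several for 1 probe, which was not named, and did not list 109 miRNA probes, which keep their probe IDs here. Old symbols were updated through the gene ID for 50 probes and through a synonym of a mouse gene for 11, with the RefSeq gene table used only for names. The ID ended in the number of the listed miRNA for 58 of the 61 probes and differed for 3, among them 1org-34c, listed as Mir34a.

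Before the data were examined, the rule was set that a correlation below -0.3 between the 2 arrays of each time point would mark channel ratios, one above 0.3 ratios already turned, and anything between no direction. The correlations were 0.66 at 72 h and -0.12 at 96 h, so the rule gave no verdict. The reading as channel 2 (Cy5) over channel 1 (Cy3), with the sign of the arrays with Foxp3 in Cy3 turned, was then taken as likely, after the data had been seen, and the counts and calls of each comparison are also given with the other reading. The 2 arrays of a time point were averaged, which cancels a dye effect that is the same on both.

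The main test was an intercept-only limma fit (limma 3.58.1 in R 4.3.3) on the averages of 72 h and 96 h over 171 miRNA probes, with Benjamini-Hochberg adjusted p under 0.05. It had 1 residual degree of freedom, and the empirical Bayes step pooled the variance of all probes to a common SD of 0.677 and a standard error of 0.479. P-values measure the spread between the time points only, which may be technical. Counts past 1.5-fold asked for a mean of that size and the same sign on both arrays of a time point, with no test. The difference between time points asked for 1.5-fold with no overlap of their arrays. On simulated data with 20 of 171 probes changed and the pooled SD, the test recovered 5.1% of probes changed by a log2 ratio of 1, 66.1% at 2 and 99.3% at 4, over 50 runs each. The simulated noise was independent, with the same SD for every probe and no shift between arrays, so these rates may not hold for these arrays.

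In all, 19 lists were fixed before the data were examined: miRNAs higher and lower in regulatory T cells, those induced and reduced by T cell activation, the miR-17, miR-23/27/24, let-7, miR-15/16, miR-30, miR-29 and miR-181 groups, and markers of erythroid, myeloid, muscle, neural, liver and pancreas, embryonic stem, epithelial and stromal or endothelial cells. The 8 with at least 3 members named by the annotation were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and each list's median was ranked among 10000 random lists of its size. Camera compares a list with the other probes, so a list with a median above 0 can be placed low. The estimated correlation and fry rest on 1 residual degree of freedom, so a call lost with them cannot decide. Named probes were up to 10 per direction with the largest mean and 1 sign on all 4 arrays, the 3 largest per direction at each time point, the measured members of both regulatory T cell lists and 3 T cell miRNAs matched by ID.

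Alternatives were centring on the miRNA median, centring and scaling, the other reading of the sign, a 2-fold threshold, each array left out, models of the 4 arrays with a dye term, robust variance, and allowance for missing values. Added after the data had been seen were centring on the U6 and tRNA probes, the natural log reading, only probes with a listed symbol, control probes included, list members matched on probe IDs, the same without a probe of the wrong arm, and list tests without the 96 h array with Foxp3 in Cy5 and with the other reading of the sign.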

Results

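MicroRNA levels were compared between mouse activated T cells transduced with Foxp3, the transcription factor that defines regulatory T cells, and activated T cells transduced with a control vector. Both RNAs were hybridised together to 2-colour microRNA arrays at 72 h and at 96 h, with 2 arrays of opposite dye assignment at each time point and 4 arrays in all. Replicate 1 of each time point had the Foxp3 RNA in Cy5 and replicate 2 had it in Cy3. The value table held 1 log ratio per probe and array for 178 probes with no missing value, 171 of them for miRNAs and 7 for control RNAs (U6 and other small nuclear RNAs, and tRNAs). The 2 arrays of a time point shared their RNAs and were averaged as 1 replicate, so n was 2 time points, and SDs below are between these. No label said whether the time points came from separate cultures. The number of arrays limits the precision of every value.

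The direction of the ratios was not settled, and likely below only names the reading that was taken. Each value was read as Cy5 over Cy3, because Cy5 was channel 2 on every array, and the sign was turned on the arrays with Foxp3 in Cy3, so that positive values stand for a level likely higher with Foxp3. Across the 171 miRNA probes, which are not independent replicates, the deposited values of the 2 arrays correlated at r = 0.66 at 72 h and r = -0.12 at 96 h. A reversed dye assignment would give a negative correlation where the samples rather than the dyes set the ratios. After turning, 48 of 171 probes had the same sign on both 72 h arrays and 96 of 171 on both 96 h arrays, where chance gives 85.5 (50%); centred on the miRNA medians, the counts were 27 and 116. The array of 96 h with Foxp3 in Cy5 stood apart, with a deposited median of 1.27 against -0.59, -0.83 and 0.02 on the other 3 arrays. The turned ratios had a median of 0.07 at 72 h and 0.80 at 96 h, and centring each array on its miRNA median lowered them by 0.12 and 0.62.

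**Figure D1:**
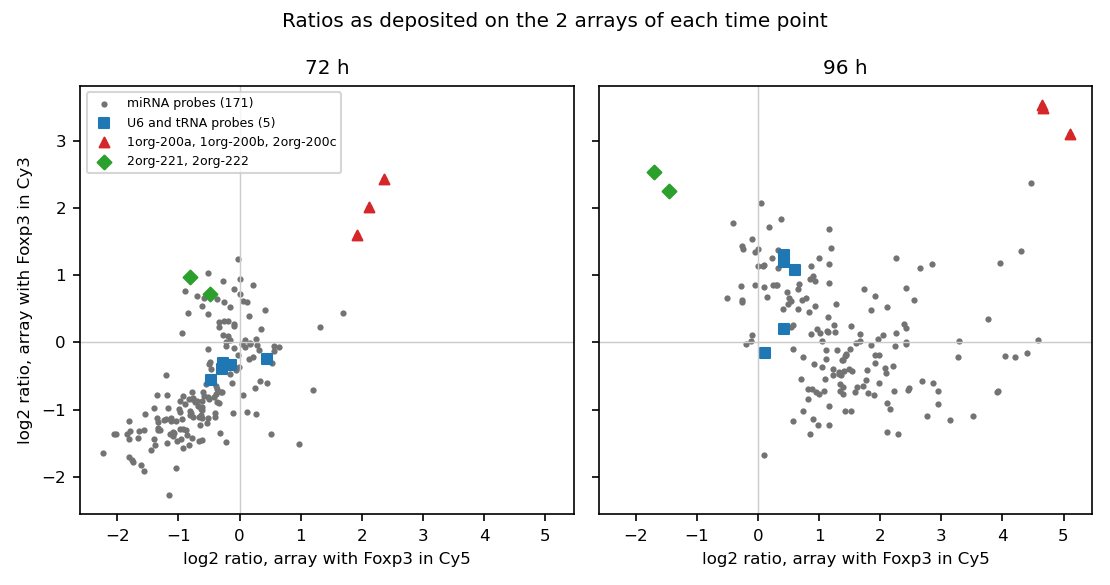
Deposited log2 ratios of the array with Foxp3 in Cy3 (vertical axis) against the array with Foxp3 in Cy5 (horizontal axis) at 72 h (left) and 96 h (right); each point is 1 probe. Probes 2org-221 and 2org-222 (diamonds) had opposite signs on the 2 arrays of each time point, as a difference between the samples gives if the values are channel ratios. Probes 1org-200a, 1org-200b and 2org-200c (triangles) were positive on all 4 arrays.

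The first comparison asked which miRNAs differed with Foxp3 over both time points. The probes with the largest mean ratios of 1 sign on all 4 arrays were Mir31 on the likely higher side and probes 2org-222 and 2org-221, which the annotation table did not list, on the likely lower side. Mir31, fixed beforehand among the miRNAs lower in regulatory T cells, had a mean log2 ratio of 1.03 ± 0.31 (SD, n = 2), or 2.04-fold. Probe 2org-222 had a mean of -1.51 ± 0.87 (SD, n = 2), or 2.84-fold lower, and 2org-221 a mean of -1.23 ± 0.89 (SD, n = 2), or 2.34-fold lower. Mir20a, a member of the miR-17 cluster that promotes lymphocyte proliferation, followed at -0.86 ± 0.32 (SD, n = 2).

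Of the 171 miRNA probes, 13 had 1 sign on all 4 arrays, 3 of them likely higher and 10 likely lower. Even and independent signs would give 21.4 (12.5%), but signs were uneven on the single arrays, so 21.4 is no chance level here. The count and the split depended on the scaling. After centring on the miRNA medians 7 were likely higher and 6 likely lower, and after centring on U6 and tRNA 13 and 8. Of the 13 probes with 1 sign as deposited, only Mir15a and 2org-222 kept it after centring on the miRNA medians. None of the 3 likely higher probes kept it. Mir31, at 1.22 on the 96 h array with Foxp3 in Cy5, lay below that array's median of 1.27. Taken as already turned to Foxp3 over control, 12 probes had 1 sign on all 4 arrays, all of them higher. Besides Mir31, the likely higher probes were 1org-183, at 0.63 ± 0.24, and 2org-214, at 0.52 ± 0.43. Mir15a and Mir15b, relatives of miR-16 that restrain Bcl2 and the cell cycle, had means of -0.71 ± 0.19 and -0.52 ± 0.11. Mir19a, encoded beside Mir20a, had -0.49 ± 0.29, and the probe 1org-34c, listed as the p53-induced Mir34a, had -0.54 ± 0.40. The remaining likely lower probes were not listed, 1org-142-as at -0.60 ± 0.13, 2org-142* at -0.52 ± 0.10 and 1org-16 at -0.13 ± 0.04.

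No probe passed limma's adjusted p of 0.05. The lowest adjusted p was 0.307, and 16 probes, 14 likely higher and 2 likely lower, had an unadjusted limma p under 0.05 where 8.55 were expected. With each array centred on its miRNA median, limma called 2 probes, both likely lower, 2org-222 at -1.88 ± 1.22 (adjusted p = 0.000275) and 2org-221 at -1.60 ± 1.24 (adjusted p = 0.00326), and 26 probes had an unadjusted p under 0.05, 8 likely higher and 18 likely lower. Both calls rest on the pooled standard error of 0.378, which took the place of these probes' own larger spread. Centred, 2org-221 had opposite signs on the 2 arrays of 72 h. Its -0.485 on the array with Foxp3 in Cy5 lay above that array's median of -0.59. Centred on U6 and tRNA instead, limma called 0 probes, with a lowest adjusted p of 0.619. With the deposited values taken as already turned to Foxp3 over control, limma instead called 1org-200a, 1org-200b and 2org-200c, at 3.24, 3.08 and 2.93 (adjusted p = 0.00924, 0.0101 and 0.0139), and 5 probes had an unadjusted p under 0.05, all higher. Centred on the miRNA medians as well, that reading gave 7 calls, the same 3, Mir99b at 2.27, Mir206 at 1.83 and 2org-224 at 1.33 higher, and 1org-122a at -1.22 lower (adjusted p of 0.0342 or less). Without centring, in that reading the 2org-222 means were 0.09 at 72 h and 0.42 at 96 h, and the mean of Mir31 over the 4 arrays was 0.07 with signs that differed between arrays.

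**Figure D2:**
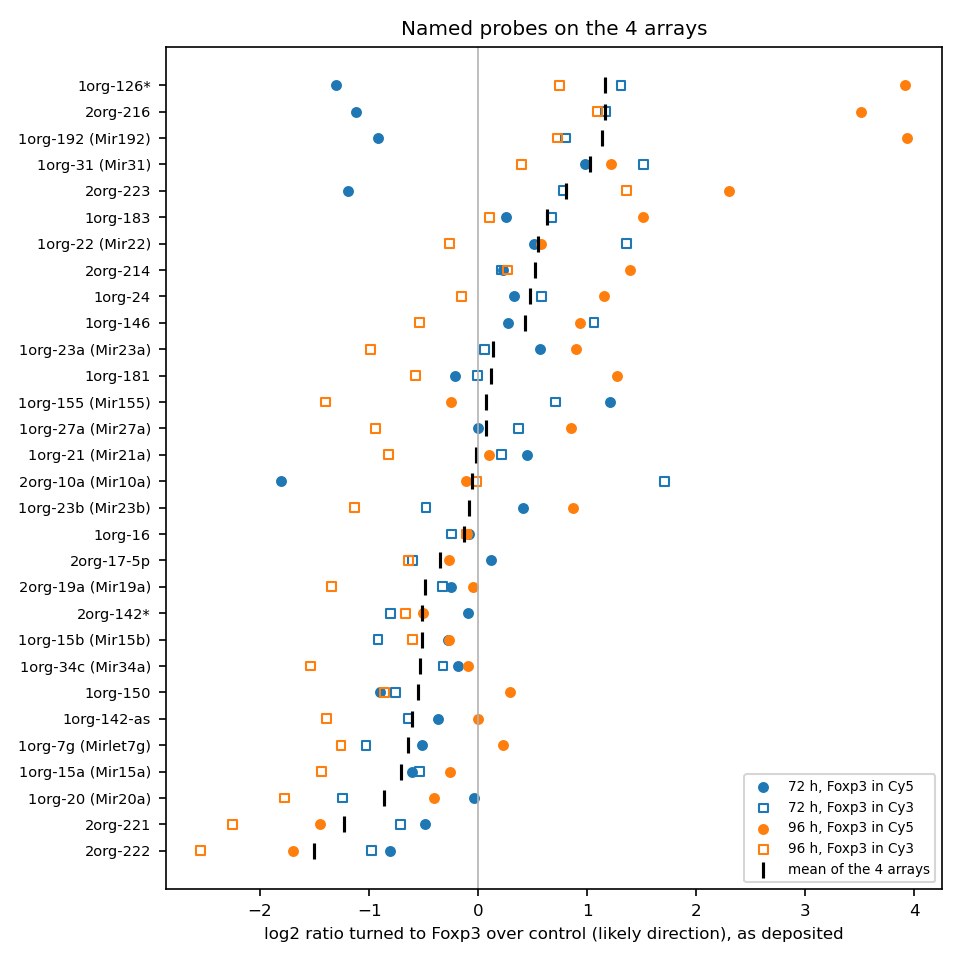
Log2 ratio of Foxp3 over control in the likely direction (horizontal axis) for the 30 named probes (vertical axis) on each of the 4 arrays; colours mark the time points, filled and open symbols the dye of the Foxp3 RNA, and the black bar the mean of the 4 arrays. Mir31 lay above 0 and 2org-222 and 2org-221 lay below 0 on all 4 arrays, while Mir155 lay above 0 on both 72 h arrays and below 0 on both 96 h arrays.

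At 72 h, the question was which miRNAs moved past 1.5-fold in both dye orientations. Mir31 was the highest at 2.38-fold (log2 1.25), followed by Mir155, which T cell activation induces and Foxp3 binds, at 1.94-fold (log2 0.96) and Mir22 at 1.91-fold (log2 0.93), all likely higher. On the likely lower side stood 2org-222 at log2 -0.90, 1org-150 at -0.83 and Mirlet7g at -0.77. In all, 13 of 171 probes passed, 4 likely higher and 9 likely lower. Centred on U6 and tRNA, 14 passed, 5 likely higher and 9 likely lower. Centred on the miRNA medians, 8 passed, 2 likely higher and 6 likely lower. With the latter centring Mir155 no longer passed, at 1.80 and -0.12 on the 2 arrays, while Mir22 still did. A single time point is 1 replicate, so these are values with no test. Read from 1 array, 124 passed without replicate 1, 105 of them likely higher, and 94 without replicate 2, 86 of them likely lower. Taken as already turned, 96 passed, 5 higher and 91 lower, and this ranking did not hold. The highest values were then those of 1org-200a at 2.40 and 1org-200b at 2.07, while Mir31 was at -0.27, Mir155 at 0.25 and Mir22 at -0.42. The lowest was Mir302a at -1.94, while 2org-222 was at 0.09, 1org-150 at -0.07 and Mirlet7g at 0.25.

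At 96 h, the largest likely higher values were those of Mir192, a miRNA typical of liver, gut and kidney, at 5.02-fold (log2 2.33), 1org-126* at 5.01-fold and 2org-216 at 4.94-fold. They rested on the array with Foxp3 in Cy5, at log2 3.93, 3.91 and 3.51, against 0.73, 0.74 and 1.10 on the other array, where 1org-122a was the highest at 1.68. Centred on the miRNA medians they were still the highest, at 3.26, 3.26 and 3.21-fold. The largest likely lower values were those of 2org-222 at 4.34-fold lower (log2 -2.12), 2org-221 at 3.61-fold lower (log2 -1.85) and Mir20a at 2.13-fold lower (log2 -1.09). In all, 88 of 171 probes passed 1.5-fold on both arrays, 79 likely higher and 9 likely lower. Probes matched by ID to miRNAs of other cell types moved with the likely higher probes, with 26 of 27 above 0 at 96 h and a median of 0.89, against 0.69 for the remaining miRNA probes and -0.24 for the U6 and 4 tRNA probes. The other small nuclear RNA controls stood at 1.09 and 1.70. At 72 h the medians were 0.10, 0.07 and 0.05, and those controls stood at -0.35 and 0.30. In the other reading of the sign, 24 of the 27 lay above 0 at 96 h and 4 at 72 h, and the medians were 0.83, 0.64 and 0.82 at 96 h and -1.15, -0.53 and -0.29 at 72 h. In the likely reading, centred on the miRNA medians, 23 of the 27 lay above 0 at 96 h, with a median of 0.265. As deposited, their 96 h median was 2.05 on the array with Foxp3 in Cy5 and -0.345, before turning, on the other. The split between directions depended on centring and on 1 array. Centred on the miRNA medians, 73 probes passed, 30 likely higher and 43 likely lower, and centred on the U6 and tRNA probes 112 passed, 108 and 4. Without the 96 h array with Foxp3 in Cy5, 97 passed on the remaining array, 41 likely higher and 56 likely lower. Taken as already turned, 58 passed, all of them higher, the highest being 2org-200c at 4.10, 1org-200b at 4.09 and 1org-200a at 4.08. In that reading Mir192 was at 1.60, 1org-126* at 1.58 and 2org-216 at 1.21. The likely lower probes were then above 0, 2org-222 at 0.42, 2org-221 at 0.40 and Mir20a at 0.68.

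The 2 time points were then compared with each other. Past 1.5-fold on the same side at both, with 1 sign on all 4 arrays, were Mir31 on the likely higher side and Mir20a, 2org-221 and 2org-222 on the likely lower side, 4 probes where independent counts would give 1.85 likely higher and 0.474 likely lower. After centring on the miRNA medians the 4 such probes were 1org-150, Mir15a, 2org-210 and 2org-222, and after centring on U6 and tRNA they were 1org-142-s, Mir31, 2org-210, 2org-221 and 2org-222. Probe 2org-222 was thus the 1 probe shared by all 3 scalings. Mir155 passed on opposite sides, at 0.96 at 72 h and -0.82 at 96 h. After centring on the miRNA medians or on U6 and tRNA, no probe passed on opposite sides. The Mir155 difference did not pass limma's Foxp3 by time term over the 4 arrays (adjusted p = 0.991), a term that passed no probe, even at 2.57. In the already turned reading, 5 probes passed on the same side, all higher, and 16 on opposite sides.

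Across the 171 miRNA probes, the turned 72 h and 96 h ratios correlated at r = 0.39 (95% confidence interval 0.26 to 0.51; Spearman rho 0.34), with a permutation p of 1e-05, the smallest that the permutations could give. Probes are not independent replicates, so this describes these arrays. Without Mir31 and 2org-222, the probes farthest from the 72 h median, r was 0.37, and with the values taken as already turned it was 0.46. The sign rested on 1 array, since r was -0.33 without 72 h replicate 2.

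**Figure D3:**
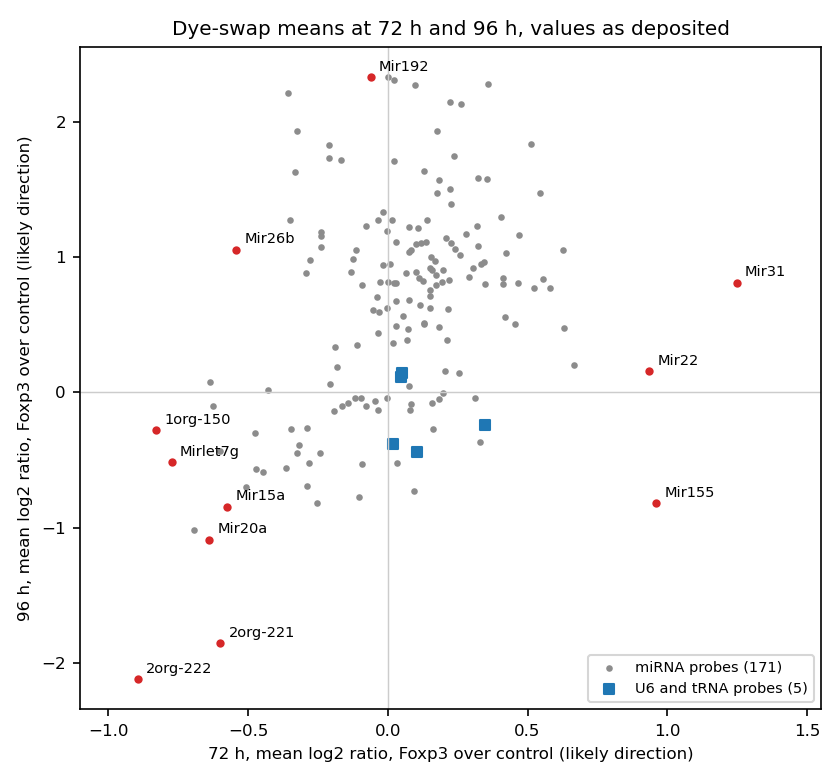
Mean log2 ratio of Foxp3 over control in the likely direction at 96 h (vertical axis) against 72 h (horizontal axis), each point a probe and the mean of 2 arrays. Probes 2org-222 and 2org-221 lay low at both time points, Mir31 lay high at both, Mir155 was above 0 at 72 h and below 0 at 96 h, and most probes lay above the U6 and tRNA probes (squares) at 96 h.

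Between 72 h and 96 h, 12 probes differed by at least 1.5-fold with no overlap between the arrays of the time points, 8 higher and 4 lower at 96 h. Among them, Mir26b, a miRNA that falls on T cell activation, went from -0.54 to 1.05 and Mir155 from 0.96 to -0.82. With each array centred on its miRNA median the count was 41, 23 higher and 18 lower, and centred on U6 and tRNA it was 81, 78 higher and 3 lower. The other reading of the sign gave 116, all higher at 96 h. With a Foxp3 by time term over the 4 arrays, limma called 0 probes as differing between the time points, and 0 had an unadjusted p under 0.05. The term had little power, as its largest difference, a log2 ratio of 2.57 for Mir299a, had an unadjusted p of 0.102.

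Groups of miRNAs were then examined by lists fixed before the data were examined, with members named through the annotation table. Of the 5 measured members of the miR-17 clusters, which promote lymphocyte growth and survival, 4 lay below 0 at both time points (Mir20a, Mir19a, Mir25 and Mir93), and Mir18 was mixed at 0.09 and -0.73. Their median log2 ratio was -0.39, which exceeded that of only 0.66% of random lists, and limma's camera placed them lower than the other probes (adjusted p = 0.00198). The call was lost with an estimated correlation (adjusted p = 0.712) and with fry, which tests the members alone (adjusted p = 0.802). Both rest on 1 residual degree of freedom and had little power, so the loss cannot decide. None of the 5 passed limma over all probes or adjusted over the list alone. Centring on the miRNA medians lowered all turned ratios of a time point by the same amount. Camera compares the list with the other probes, so its result could hardly change (adjusted p = 0.00200) and adds no support. With that shift 1 passed limma over the list alone and all 5 lay below 0 at both time points. With the values taken as already turned, the direction was opposite and the call ended, at a median of 0.47 and a camera adjusted p of 0.593.

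The let-7 family, which restrains growth genes, and the miR-15/16 family had medians below 0 but did not pass camera (adjusted p = 0.0628 for each). Of 6 let-7 members, 3 lay below 0 at both time points, among them Mirlet7g at -0.77 and -0.52 and Mirlet7d at -0.36 and -0.56, while Mirlet7e was above 0 at both and Mir98 reached 1.28 at 96 h. Of 3 miR-15/16 members, Mir15a and Mir15b lay below 0 at both time points and Mir195a above 0 at both. After centring on the miRNA medians, which lowered all turned ratios of a time point alike, all 3 miR-15/16 members lay below 0 at both time points. With that shift 1 let-7 member and 2 miR-15/16 members passed limma adjusted over the list alone, where none had before. Taken as already turned, the medians were above 0, at 0.41 for let-7 and 0.28 for miR-15/16 (camera adjusted p = 0.712 for each).

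The miRNAs listed as higher in regulatory T cells did not move as a group (7 measured, median 0.07, mean 0.09, camera adjusted p = 0.328 with the list placed low among all probes). At 72 h their median of 0.31 exceeded that of 98.2% of random lists, and at 96 h their median of -0.06 exceeded that of only 4.05%. Centring on the miRNA medians turned the median to -0.30 and the mean to -0.28, with 0.19 at 72 h and -0.69 at 96 h. In the already turned reading the median was 0.36, with 0.12 at 72 h, above 98.9% of random lists, and 0.58 at 96 h, above 28.1%. At 72 h, Mir155 and Mir22 were the highest members, and Mir21a was at 0.33 and Mir23a at 0.31, whereas the other reading put Mir23b and Mir23a highest and Mir22 at -0.42. Mir23b averaged -0.03 from 0.41 and -0.48 on the 2 turned arrays, and Mir10a averaged -0.05 from -1.80 and 1.71. At 96 h Mir21a was at -0.36 and Mir27a at -0.05, against 0.18 at 72 h. Among members known only by probe ID, 1org-146 had 0.67 at 72 h and 0.20 at 96 h, 1org-24 had 0.45 and 0.50, and 2org-223, which ends in the number of a myeloid miRNA, had -0.21 and 1.83. Mir31 was the 1 member matched to a probe in the list lower in regulatory T cells. It lay on the likely higher side, opposite to the list's name, and passed limma adjusted over the list alone, which for 1 member is the unadjusted p. It did not pass after centring on the miRNA medians, where its mean was 0.66 and its 96 h value 0.19, nor when taken as already turned. The list also held both arms of miR-142, which matched no probe by name. Probes with that number went both ways, with means of -0.60 for 1org-142-as and -0.52 for 2org-142* against 0.55 for 1org-142-s.

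Of 8 measured miRNAs induced by T cell activation, 3 lay above 0 at both time points (Mir182, Mir96 and Mir212), 2 below 0 at both (Mir19a and Mir20a) and 3 were mixed, with a median of 0.03, a mean of -0.05 and a camera adjusted p of 0.0628. The 3 measured miRNAs reduced by activation, Mir26b, Mir29a and Mir30e, had a median of 0.26 (adjusted p = 0.627), and the miR-23/27/24 clusters, with 3 members, had a median of 0.07 (adjusted p = 0.407). Centring on the miRNA medians turned these 3 medians to -0.35, -0.12 and -0.30, with 2 of the 8 induced miRNAs above 0 at both time points, 4 below and 1 passing limma adjusted over the list alone. The other reading of the sign gave 0.32, -0.15 and 0.60 (camera adjusted p = 0.712, 0.712 and 0.593). In the T cell miRNAs followed by probe ID, 1org-181 was at -0.11 and 0.35 and 2org-17-5p at -0.24 and -0.45. Matched on probe IDs instead, camera placed 4 lists lower, those induced by activation (18 probes, adjusted p = 0.00102), the miR-17 clusters (10, 0.00303), let-7 (9, 0.00398) and miR-15/16 (4, 0.0394). Such calls, like that for the miR-17 clusters by annotation, are relative to the other probes. At 96 h the median of all miRNA probes was 0.805, against -0.24 for U6 and tRNA. Camera cannot tell lower list members from raised other probes, so the calls do not show lower levels with Foxp3. The older name of miR-17-5p also took in 2org-17-3p, a probe for the other arm, and without it the activation list had 17 probes and an adjusted p of 0.000192. With an estimated correlation, again from 1 residual degree of freedom, camera's adjusted p was 0.849 for each of the 4. With the values taken as already turned, none of the 4 was called by camera (adjusted p = 0.517 to 0.808). In that reading camera placed the epithelial list higher (6 probes, adjusted p = 6.56e-07), a call lost with an estimated correlation (adjusted p = 0.943).

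Lists with 1 measured member had no list test. Mir30e of the miR-30 family had a mean of 0.38 and Mir29a of the miR-29 family a mean of -0.05, and the miR-181 family, matched by ID, had a median of 0.33 over 2 probes. Among markers of other cells, the 5 embryonic stem cell miRNAs had a median of 0.41 (camera adjusted p = 0.627), being 0.02 at 72 h and 0.85 at 96 h. It was 0.04 after centring on the miRNA medians and -0.58 in the other reading (camera adjusted p = 0.621 and 0.164). Single members were Mir144 for erythroid cells at 0.17 and 1.93, Mir206 for muscle at 0.55 and 1.47, Mir203 for epithelium at 0.15 and 0.71, and Mir143 for stroma at 0.28 and 1.17. Mir144 and Mir206 passed limma adjusted over the list alone, again the unadjusted p of 1 member. They did not pass after centring on the miRNA medians, where their means were 0.68 and 0.64. With the values taken as already turned Mir206 alone passed. The turned arrays of Mir206 disagreed in sign, at 1.32 and -0.23 at 72 h and 4.30 and -1.36 at 96 h. Those of Mir144 disagreed at 72 h, at -0.76 and 1.11, but not at 96 h. By probe ID, the neural list (6 probes) had a median of 0.93 at 96 h, the liver and pancreas list (3 probes) 0.89, and the myeloid list (1 probe) 1.83. At 72 h the neural probes ran from -0.35 to 0.24, the liver and pancreas probes from -0.0045 to 0.10, and the myeloid probe was at -0.21. Centred on the miRNA medians, at 96 h the neural probes ran from -0.63 to 0.65, the liver and pancreas probes from -0.0035 to 1.68, and the myeloid probe was at 1.20.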

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

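All tests in this part were chosen after the result was seen. The Mir155 probe was above 0 on both 72 h arrays and below 0 on both 96 h arrays, in the likely direction, and its 96 h minus 72 h log2 ratio was -1.78. This difference did not pass limma's Foxp3 by time term over the 4 arrays (adjusted p = 0.991), which counts technical spread, and with replicate cultures it was not tested. That term cannot decide, since it passed no probe, even at its largest difference of 2.57 (limma unadjusted p = 0.102). The pattern held only in the likely direction, as with the values taken as already turned the means were 0.25 at 72 h and 0.58 at 96 h, both above 0. An exchange of the RNAs or dyes on the 96 h arrays, which would have turned the other probes too, stays open. Across them the 72 h and 96 h ratios correlated at r = 0.44 (95% interval 0.31 to 0.55), but at -0.31 without 72 h replicate 2, and the highest correlation between single arrays, 0.80, was between the arrays with Foxp3 in Cy3, which a shared dye effect also gives. A difference in level between arrays stays open too. Its means kept opposite signs with a gap of 1.42 after centring on U6 and tRNA and of 2.28 after centring on the miRNA medians, but in the second case 1 of the 72 h arrays fell to -0.12. A change of Mir155 between the time points in Foxp3-transduced or in control cells may also account for it and stays open, since each time point is 1 replicate.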

How the results depend on the processing

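Centred on the miRNA medians, limma called 2 probes, 8 passed 1.5-fold at 72 h and 41 differed between time points; centred and scaled, 29 differed, and centred on U6 and tRNA, 81. Taken as already turned, limma called 3, 96 passed at 72 h, 58 at 96 h, and 116 differed. At 2-fold, 1 passed at 72 h, 49 at 96 h and 0 at both. Over listed symbols only, 7, 29 and 2 passed and 6 differed, with fewer probes tested. Read as natural logs, 25 passed at 72 h and 9 at both. With no model, 13 probes had 1 sign on all 4 arrays. Camera's 1 called list became 0 with an estimated correlation, 0 with fry, 0 when taken as already turned and 4 with members matched on probe IDs, also 4 without 2org-17-3p in the activation list. The camera call for the miR-17 clusters held without the 96 h array with Foxp3 in Cy5 (adjusted p = 0.0157). Leaving out 1 array in turn, so that a time point rested on 1 dye orientation, gave 0 to 94 limma calls, 13 to 124 probes past 1.5-fold at 72 h, 88 to 133 at 96 h, 3 to 81 at both, and 22 to 120 that differed. The 94 calls came without 72 h replicate 1 (89 likely higher, 5 likely lower); without 96 h replicate 1 the 3 calls, all likely lower, were 1org-200a, 1org-200b and 2org-222. The correlation of the time points ran from -0.328 to 0.613, and it was reversed, at -0.328, without 72 h replicate 2. Beyond the construction of each setting, the cause was not tested.

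Replicate numbers stood for the dye orientation. With it as a replicate block over the 4 arrays and a Foxp3 by time term, limma called 0 probes for Foxp3, with 0 at an unadjusted p under 0.05, and 3 for the dye (1org-200a, 1org-200b and 2org-200c). A fit with the time point as a random block could not be fitted on 4 arrays, and a restriction to mouse-named probes was not run, since IDs carry no species. Allowing missing values moved nothing, as none were missing. Of the 30 named probes, the sign of the mean changed for 4 after centring and for 17 when taken as already turned. Signal over background was not used here, so dim probes could not be told from bright ones.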

Other observations

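All tests in this part were chosen after the result was seen. Among probes outside the named ones, 2org-210 lay below 0 on 3 of 4 arrays in the likely direction, at -0.69 at 72 h and -1.01 at 96 h. Of the miRNAs induced by T cell activation and followed by probe ID, 1org-132 had -0.09 and -0.53. Mir99b was high on both arrays with Foxp3 in Cy5, at 1.69 and 4.47, and low after turning on both with Foxp3 in Cy3, at -0.43 and -2.37. Mir26b was below 0 on both 72 h arrays and above 0 on both 96 h arrays, 1.60 apart, but did not keep these signs on every array when centred on the miRNA medians.

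In the likely direction more probes passed 1.5-fold at 96 h (88) than at 72 h (13), but the order was the opposite with the values taken as already turned (58 and 96). Read from single arrays, with no second array to share a sign, the counts were 97 and 133 at 96 h and 94 and 124 at 72 h. Within the likely reading, a difference in level between arrays is argued against as the whole cause, since after centring the 96 h count was still 9.12 times the 72 h count. An opposite sign of the 96 h array with Foxp3 in Cy5 is argued against as the whole cause too, since with its sign turned 58 probes passed at 96 h, 4.46 times the 72 h count. All 58 were then likely lower, against 79 likely higher and 9 likely lower as read, so this sign sets the 96 h direction. Whether its sign is opposite stays open. Its Spearman correlations with the other 3 arrays, as deposited, were -0.21, -0.37 and -0.33, and its Pearson correlations were 0.07, -0.20 and -0.12. Probes 1org-200a, 1org-200b and 2org-200c went the other way, being positive on all 4 arrays as deposited. Both ratios hang on the shared sign, which 27 of 171 centred probes had at 72 h and 116 at 96 h. Disagreement of the 72 h arrays thus held the 72 h count down, and neither ratio shows more change at 96 h. A trend with signal strength cannot be told apart from other causes, because brightness was not measured here, and probes matched to miRNAs of other cell types, expected to be dim in T cells, lay 0.20 above the other miRNA probes at 96 h, at the 86.7 percentile of random sets. A stronger effect of Foxp3 at 96 h stays open. No probe passed limma's Foxp3 by time term over the 4 arrays (adjusted p of at least 0.991), but that term cannot decide. Even its largest difference, 2.57 for Mir299a, had an unadjusted p of 0.102.

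Probes 1org-200a, 1org-200b and 2org-200c were high on all 4 arrays whichever dye the Foxp3 RNA carried, with means as deposited and centred from 2.72 to 3.54. A dye or label bias of these probes may account for this if the values are channel ratios, and a level higher with Foxp3 may do so if they were already turned. These cannot be told apart, because no value outside the ratios shows whether signs were turned.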
